A study of Caenorhabditis elegans with 2 samples.

How the data were processed

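Tagged CEH-82 was assayed by ChIP-seq in whole L1 larvae of 1 transgenic line, with 2 biological replicates that the labels number 1 and 2. Chromatin was fragmented by sonication, per the labels. No control library was analysed here, although the labels name a possible control experiment.

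The authors aligned reads to ce10 and to ce11 and called peaks for each build, per the file headers. For each build there was a relaxed list for each replicate, a relaxed list for both replicates pooled, and a list thresholded by irreproducible discovery rate, which compares the ranks of peaks between replicates. The aligner, the peak caller, its version and the threshold are not given in the sources used here. The deposited lists give each peak's interval, its signal, which is the authors' score and is never negative, its summit and the -log10 of its q value, as the authors calculated them. The -log10 q values were at the list's ceiling of 3.81 for all 2052 thresholded peaks on ce11 and were not used to rank. Signal scales differ between lists, and the score was used within a list, except where the replicates were compared peak by peak. The relaxed lists, which serve as input to that threshold per the file headers, held exactly 30000 peaks for the pooled replicates and for replicate 2, on both builds, and 16551 for replicate 1 on ce11. Whether a limit on list size was set is not given in the sources used here. Read depth was not given in the sources used here, and Wilson intervals at 95% cover counting error only.

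Peaks on ce11 were used with the WBcel235 sequence (RefSeq) and annotation (Ensembl release 115), whose chromosomes extend past the last peak on each of the 6 nuclear chromosomes. The ce10 lists were used for counts and recovery only, and no coordinate was converted between builds. Promoter windows ran from 1000 bp upstream to 200 bp downstream of each annotated transcript start of a protein-coding gene. The background for peak classes was the 27933 relaxed pooled peaks that overlap no thresholded peak. They share mappability with the thresholded peaks and include 1157 peaks at the highest q. The authors label the relaxed lists as peaks and background, so a part of these entries may be background and not weak binding. The background for gene lists was all protein-coding genes of the nuclear chromosomes.

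Shares were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment within each family (6 chromosomes, 5 annotation classes, 6 noncoding classes, 25 gene lists) at a threshold of 0.05, with Wald intervals for odds ratios, where 0.5 was added to each cell if any was 0. Motifs were searched on both strands in 100 bp windows at summits and 300 bp to the right of the same summits, with an exact McNemar test over 22 motifs. Replicates were compared by overlap of at least 1 bp, by correlation of log2 signal over peaks with 100000 permutations, and by overlap of their strongest peaks against 1000 random draws. The gene lists were made from gene names, so members with other names are missed.

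The rule for which genes to name was set before the data were examined, and the genes it gives follow from the data. It takes the gene with the nearest protein-coding start to each of the 15 strongest thresholded peaks or a noncoding gene within 200 bp of the summit, then ceh-82 and unc-119, then up to 4 members of each list or noncoding class with the strongest peak. Genes sharing a peak with one of these, and com-1, are named only to say where a peak lies. The tests of the report, the lists, the motifs and most alternatives were fixed before the data were examined. The alternatives were a stricter peak threshold (signal above the median), other rules of overlap, other windows, distances, flanks and backgrounds, and leaving out each replicate by using the 2052 strongest relaxed peaks of the other alone. Another 5 alternatives were chosen after seeing the data.

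The tests were checked on simulated data. In 20 random draws of 2000 relaxed-only peaks, 1 of 120 chromosome tests, 0 of 100 annotation class tests and 0 of 120 noncoding class tests passed. Planted promoter and tRNA peaks were recovered in 20 of 20 draws each. With peaks planted at members of 3 lists among 19973 genes, 60 of 60 planted and 3 of 440 other lists passed as higher. A motif planted in a part of 1000 windows at random positions was recovered in 20 of 20 draws, with 2 of 420 other motif tests passed. Random positions lack the difference in G and C content between real summits and their flanks, so this check does not cover it. The permutation tests, on 500 simulated values, recovered 20 of 20 correlations and 19 of 20 shifts of the median, with 1 of 20 passing without an effect in each.

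Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9, with random seed 20.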

Results

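Chromatin bound by the homeodomain protein CEH-82 was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole first-stage (L1) larvae of the nematode Caenorhabditis elegans. The animals carried an extra-chromosomal array with the ceh-82 gene, also called F45C12.2, fused at its 3′ end to a GFP-FLAG tag, in an unc-119 mutant background. There was 1 group of samples with 2 biological replicates, and no treatment or other strain to compare. The question the assay addresses is where in the genome the tagged protein is found. The values are peak lists from the authors' own peak calling. Peaks were called in each replicate and on both replicates pooled, and a thresholded list of peaks held to be reproducible was taken from the pooled list. Read depth was not given in the sources used here, so its effect on precision is unknown, and the intervals given below cover the counting of peaks, genes and windows only. All coordinates are on ce11 (WBcel235) and count from 1.

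The thresholded list held 2052 peaks with a median width of 230 bp (range 58 to 264), which covered 0.452% of the nuclear chromosomes. Their signal, the authors' score for each peak, ran from 22.3 to 406 with a median of 39.8. The pooled relaxed list, which the authors label as peaks and background, held 30000 entries with -log10 q down to 0.0561. The relaxed lists of replicates 1 and 2 held 16551 and 30000. The thresholded peaks were the 2052 peaks of highest signal in the pooled list. Signal scales differ between lists, so signal is used here to rank or describe peaks within a list, except where the replicates are compared peak by peak. On the older build ce10 the thresholded list held 2087 peaks, with a median width of 230 bp and a median signal of 39.5.

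Both replicates placed the strongest peaks at the same genes. The peak upstream of rpl-3, which encodes a large-subunit ribosomal protein, ranked 2 of 16551 in replicate 1 and 2 of 30000 in replicate 2, and that upstream of cdc-48.1, which encodes an AAA ATPase of protein quality control, ranked 1 and 3. Of the 2052 thresholded peaks, 1936 overlapped a relaxed peak of replicate 1 by at least 1 bp (94.3%, 95% Wilson interval 93.3 to 95.3), and 2051 overlapped one of replicate 2 (99.95%, 99.7 to 99.99). The relaxed pooled peaks that overlapped no thresholded peak, 27933 in number and called relaxed-only peaks here, were recovered less often, at 25.1% in replicate 1 and 71.2% in replicate 2. The thresholded list was chosen on these same libraries, so its recovery is not independent evidence.

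Over the 1935 thresholded peaks matched in both replicates, log2 signal was correlated across peaks, with Pearson's r of 0.665 and Spearman's rho of 0.616 (two-sided permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Peaks are not independent replicates, and these values describe the only 2 libraries. Replicate 2 scores were higher, by a median of 3.46-fold, and the log2 difference between replicates had an SD of 0.73 across peaks. The fold may be a matter of scale between the lists and is not read as more binding. Of the 2052 peaks of highest signal in replicate 1, 1430 (69.7%) overlapped one of the 2052 of highest signal in replicate 2. Random draws from the relaxed list of replicate 2 gave a mean of 6.44% (one-sided permutation p = 0.000999, the smallest that 1000 draws can give).

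**Figure D1:**
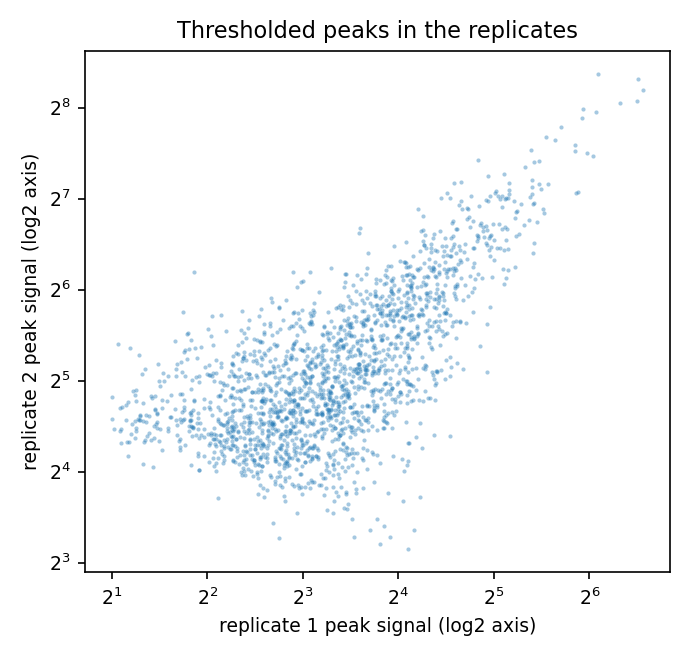
Signal of the best overlapping relaxed peak in replicate 1 (horizontal, log2 axis) and replicate 2 (vertical, log2 axis) for the 1935 thresholded peaks found in both, each point a peak, in the authors' signal units. The peaks rise together (rho 0.616), and replicate 2 scores lie higher by a median of 3.46-fold, which may be a matter of scale between the lists.

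Peaks lay mainly just upstream of protein-coding genes. A summit fell within 1000 bp upstream to 200 bp downstream of an annotated protein-coding transcript start for 1439 of the 2052 thresholded peaks (70.1%, 68.1 to 72.1), against 30.6% of relaxed-only peaks (odds ratio 5.33, 95% interval 4.83 to 5.88, Fisher's exact test, adjusted p = 9.05e-274). Exons held 11 thresholded summits (0.536% against 19.97%, odds ratio 0.0216), and introns held 183 (8.92% against 25.3%, odds ratio 0.289). Intergenic sequence held 16.3% against 21.7% (odds ratio 0.703), and noncoding RNA genes 4.09% against 2.42% (odds ratio 1.72). All 5 classes passed the two-sided test after Benjamini-Hochberg adjustment, but with the stricter peak threshold the noncoding RNA gene class was at 0.967 and did not pass. Each summit was given to the first class it met in the order promoter, noncoding RNA gene, exon, intron and intergenic sequence.

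The median thresholded summit was 183.5 bp upstream of the nearest protein-coding start, and 82.7% of summits were upstream of it, against 48.8% of relaxed-only summits. Promoter peaks were also stronger, with a median signal of 43.2 (interquartile range 30.05 to 66.97) in 1439 promoter peaks and 35.9 (27.3 to 47.7) in the other 613. The difference of median log2 signal was 0.27 (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). It was 0.15 with the signal of replicate 1 alone (permutation p = 0.0097) and 0.15 with a promoter window of 2000 bp upstream (permutation p = 0.00901).

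**Figure D2:**
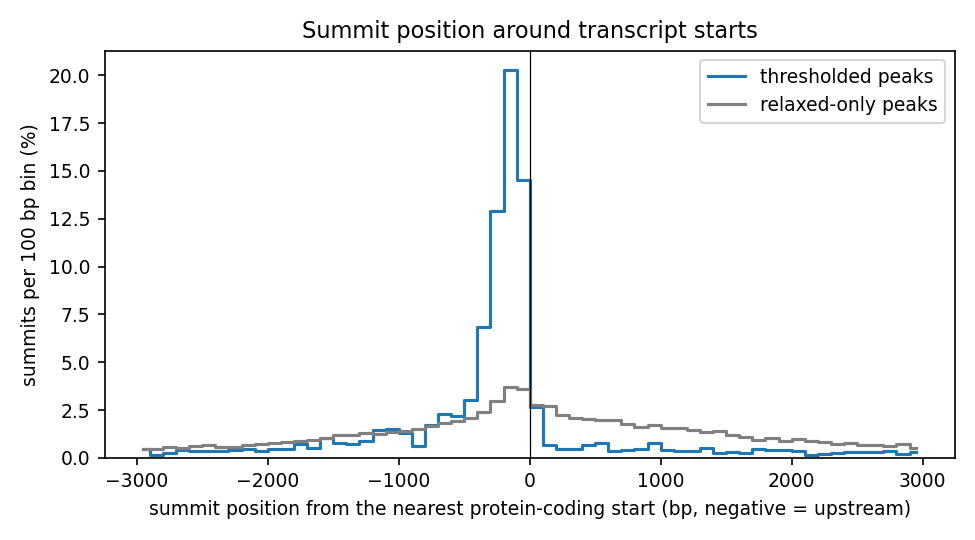
Percent of summits in each 100 bp bin (vertical) by signed distance in bp from the nearest protein-coding transcript start (horizontal, negative upstream), for thresholded peaks (blue) and relaxed-only peaks (grey). Thresholded summits are most frequent in the bin that starts 200 bp upstream, which holds 20.3% of them against 3.68% of relaxed-only summits.

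The chromosomes did not share the peaks in the proportions of the relaxed-only peaks. Chromosomes I and III held more, with 394 peaks (19.2% against 15.2%, odds ratio 1.33, 1.18 to 1.49) and 392 peaks (19.1% against 15.2%, odds ratio 1.32, 1.17 to 1.48). Chromosome V held 296 (14.4% against 17.8%, odds ratio 0.777, 0.685 to 0.883), and the X chromosome 347 (16.9% against 21.5%, odds ratio 0.744, 0.661 to 0.838). These 4 passed the threshold of 0.05 (adjusted p from 4.18e-06 to 0.000109, Fisher's exact test over 6 chromosomes), while chromosomes II (odds ratio 1.01) and IV (0.993) did not. Against chromosome length instead of relaxed-only peaks, the X odds ratio was 0.948 and no longer passed. The middle 33.3% of each autosome by length, the less recombining part, held 40.9% of thresholded and 38.9% of relaxed-only autosomal peaks, a difference that did not pass the test (odds ratio 1.09, 0.986 to 1.20, Fisher's exact test, p = 0.094). Against chromosome length it passed, with an odds ratio of 1.39 (exact binomial test, p = 6.19e-11).

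Of the 15 peaks of highest signal, 7 had a ribosomal protein gene in the window. The first was on chromosome III at 3867490 to 3867658, with its summit 277 bp upstream of the start of rpl-3 (WBGene00004414, 3867854 to 3869587, plus strand) and a signal of 406. The 60 bp around that summit, 3867547 to 3867606, read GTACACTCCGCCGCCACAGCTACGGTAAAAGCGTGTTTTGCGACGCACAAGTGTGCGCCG. Further peaks lay 346 bp upstream of rpl-15 (signal 399), in the windows of both Y17G9B.5 and rpl-20 on chromosome IV (357), 450 bp upstream of rpl-35 (347), 260 bp upstream of rps-1 (295, within 200 bp of the noncoding genes F56F3.10 and F56F3.11), at ska-3 and rps-12 (276), and 23 bp upstream of rpl-12 in a window shared with lin-54 (240). The remaining promoter peaks were those of cdc-48.1 (383), tasp-1 (314), eelo-2 (313), nspc-17 (243) and cox-5A (243), the last a gene for a subunit of cytochrome c oxidase.

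The other 3 of the 15 were intergenic and all on the X chromosome, with summits at 806677 (signal 250), 4209270 (249) and 11094217 (247). The nearest protein-coding starts were those of gtr-1, 3899 bp away, F20B6.9, 1785 bp away, and W02H3.3, 3969 bp away. The 60 bp around the first of these, 806647 to 806706, read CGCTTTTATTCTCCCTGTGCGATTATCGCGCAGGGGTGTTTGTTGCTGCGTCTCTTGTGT. Each of the 3 overlapped a peak ranked within the first 18 in both replicates.

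Of the 25 gene lists, 7 had peaks at their starts more often than other genes. Of 81 ribosomal protein genes, 65 had one (80.2%, 70.3 to 87.5), against 9.63% of other protein-coding genes (odds ratio 38.1, 22.02 to 66.04, adjusted p = 3.72e-49, Fisher's exact test over 25 lists). Translation factors followed with 18 of 31 (58.1%, odds ratio 12.7), then respiratory chain and ATP synthase genes with 21 of 38 (55.3%, odds ratio 11.3), and proteasome genes with 18 of 33 (54.5%, odds ratio 11.0). In all, 1980 of 19973 protein-coding genes had a peak (9.91%), from 1439 peaks, of which 556 lay in the windows of at least 2 genes. The 65 ribosomal protein genes shared 63 distinct peaks. With only the peaks that lie in the window of a single gene, an alternative chosen after seeing the data, the odds ratios fell to 7.47 for ribosomal protein genes, 6.99 for respiratory chain genes, 6.56 for translation factors and 4.99 for proteasome genes. Against only the genes with a relaxed summit they were 17.4, 7.95, 6.12 and 5.10 in the same order. All of these passed.

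Among the translation factors, the strongest peaks were those of eif-3.C, a subunit of an initiation factor (signal 178), eef-2 (129) and eef-1A.1 (114), which encode elongation factors, and eef-1B.1 (100). In the respiratory chain list, cox-5A (243) was followed by cox-6B (201), atp-1, for a subunit of ATP synthase (136), and cox-5B (125). The proteasome list was led by rpn-3 (169), which shares its peak with hsp-110, then rpn-11 (103), rpt-2 (82.7) and pbs-1 (64.5). These 3 lists passed the exact test with adjusted p of 2.89e-10, 3.42e-11 and 9.57e-10.

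Another 3 lists passed in the same direction. Cell cycle and DNA replication genes had peaks at 13 of 39 (33.3%, odds ratio 4.57, exact test, adjusted p = 0.000184), led by pcn-1, the sliding clamp of DNA polymerase (signal 122), cdc-6, a replication licensing factor (110), cdk-5 (94.1) and cdk-7 (79.1). Vacuolar ATPase genes, for the proton pump of acidic organelles, had peaks at 7 of 20 (35.0%, odds ratio 4.91, exact test, adjusted p = 0.00513), among them vha-1 (73.6), vha-8 (72.6), vha-12 (70.6) and vha-15 (47.1). Heat shock protein genes had them at 6 of 22 (27.3%, odds ratio 3.42, exact test, adjusted p = 0.0336), led by hsp-110 (169), hsp-90 (163), hsp-1 (125) and hsp-60 (120), which encode chaperones. The vacuolar ATPase call was lost with the peaks of replicate 1 alone (odds ratio 3.32), against genes with a relaxed summit (2.63) and without the X chromosome (3.62), the last chosen after seeing the data here and below. The heat shock protein call was lost with the peaks of replicate 1 alone (2.93), with 500 bp (3.30) and 2000 bp windows (2.60), without the X chromosome (3.10) and with peaks in the window of a single gene (2.24). The cell cycle call was lost in the last of these (2.56).

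Several large gene families had peaks less often than other genes. Chemoreceptor genes had peaks at 8 of 1309 (0.611%, odds ratio 0.052, exact test, adjusted p = 6.91e-48), C-type lectins at 2 of 240 (0.833%, odds ratio 0.0754), neuropeptides at 1 of 102 (0.98%, odds ratio 0.0895) and cuticle collagens at 4 of 156 (2.56%, odds ratio 0.238). F-box genes had them at 9 of 322 (2.80%, odds ratio 0.258), nuclear hormone receptors at 15 of 274 (5.47%, odds ratio 0.523) and homeobox genes at 3 of 93 (3.23%, odds ratio 0.302, exact test, adjusted p = 0.0421). The exceptions included sri-5 (signal 142) and srh-16 (110) among the chemoreceptors, clec-53 (55.4), nlp-4 (33.0), col-71 (72.7), fbxb-58 (190) and nhr-47 (118). The fbxb-58 summit lay 1000 bp upstream, at the outer edge of the window. The 3 homeobox genes were ceh-38 (70.9), ceh-39 (47.2) and unc-62 (22.6), of which ceh-39 (rank 3782) and unc-62 (3991) lay outside the strongest 2052 peaks of replicate 1. The test of this list was lost with the peaks of replicate 2 alone (odds ratio 0.304), the stricter peak threshold (0.364), 500 bp windows (0.372) and without the X chromosome (0.262). The cuticle collagen call was lost with the stricter threshold (0.324) and the F-box call against genes with a relaxed summit (0.487). With peaks in the window of a single gene, fewer peaks remained and the tests of neuropeptide (0.108), homeobox (0.490) and nuclear hormone receptor genes (1.11) did not pass.

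The lists named for single tissues did not pass the test. There were peaks at 0 of 18 pharynx genes (upper 95% limit 17.6%), 0 of 20 intestine genes (16.1%), 3 of 18 body-wall muscle genes, 7 of 63 hypodermis and moulting genes, 5 of 25 neuronal genes and 2 of 31 germline genes, with adjusted p from 0.158 to 0.869. Neuronal genes passed as higher with the peaks of replicate 1 alone (odds ratio 3.15) and with 2000 bp windows (3.90). The muscle peaks were those of act-4 (signal 40.3), unc-112 (34.5) and unc-45 (34.2), where act-4 (rank 2083) and unc-112 (2567) lay outside the strongest 2052 peaks of replicate 1, and the neuronal ones were led by snb-1, which encodes synaptobrevin (155), and sbt-1 (46.7). The strongest hypodermis members were dpy-23 (40.2), dpy-27 (30.1), dpy-30 (29.8) and dpy-26 (29.1), of which dpy-27, dpy-30 and dpy-26 are known as dosage compensation genes. The list was made from gene names, so its members are not all markers of that tissue. The dpy-27 summit lay at -683 bp from the start of the gene, and its best peak in replicate 1 ranked 13969 of 16551, so it rests mainly on replicate 2. The germline members were mes-2 (88.6) and nos-3 (65.0).

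Histone genes had peaks at 7 of 72, led by his-37 (signal 190), and bHLH factors at 2 of 28, hlh-11 (55.2) and hlh-30 (30.8), both outside the strongest 2052 peaks of replicate 1 (ranks 6067 and 5476). Insulin-like peptide genes had 1 of 39, ins-39 (189), aminoacyl-tRNA synthetase genes 6 of 32, led by ears-2 (118.6), and the insulin signalling pathway 1 of 10, daf-16 (36.6). None of these 5 lists passed (adjusted p from 0.198 to 1).

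**Figure D3:**
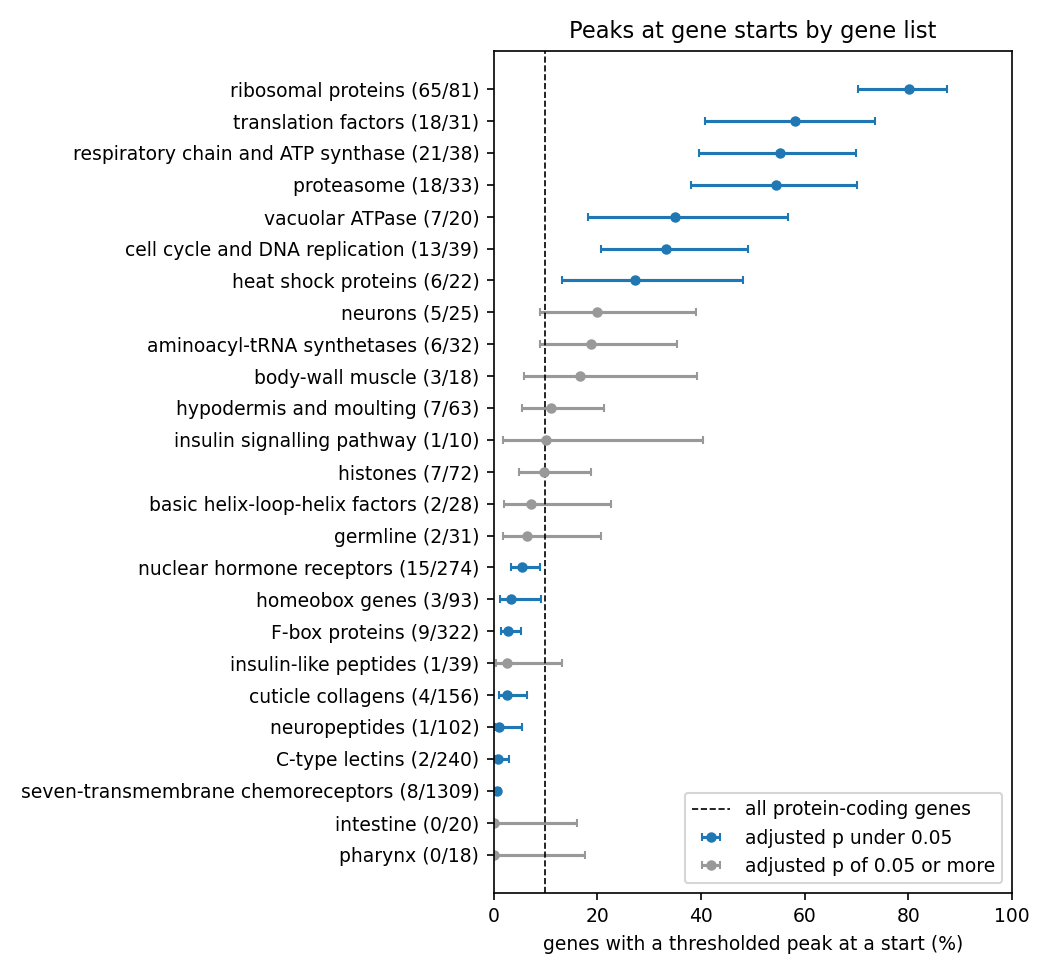
Percent of genes in each of the 25 lists with a thresholded summit at a transcript start (points, with 95% Wilson intervals as bars), and the share over all protein-coding genes (dashed line, 9.91%). Blue points passed the adjusted threshold. Ribosomal protein genes stand highest at 80.2%, and the chemoreceptors lie at 0.611%.

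Small noncoding RNA genes were also sites of peaks. Within 200 bp of a tRNA gene lay 102 thresholded summits (4.97% against 0.848% of relaxed-only summits, odds ratio 6.11, 4.82 to 7.74, Fisher's exact test, adjusted p = 2.90e-38), which reached 109 of 612 tRNA genes (17.8%). For snoRNA genes, whose products guide modification of ribosomal RNA, there were 74 summits (3.61% against 0.337%, odds ratio 11.1, 8.14 to 15.1, exact test, adjusted p = 1.37e-40), at 75 of 346 genes. For snRNA genes there were 16 summits (0.78% against 0.0931%, odds ratio 8.43, 4.52 to 15.7, exact test, adjusted p = 9.87e-09), at 17 of 129 genes. The strongest of these were sls-2.4 (signal 166) and sls-2.2 (148), which encode SL2 RNAs that are spliced onto messages of operons.

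The strongest snoRNA peaks were those at Y53F4B.47 (signal 137), ZK994.7 (128), F39B2.14 (125) and F59C6.15 (113). The strongest tRNA peaks were weaker, with 82.7 at a pair of tRNA genes on the X chromosome (WBGene00023110 and WBGene00023111) and 77.1 at WBGene00000308. MicroRNA genes had 8 summits (0.39% against 0.175%, odds ratio 2.23, exact test, adjusted p = 0.0682), which did not pass in this test and did so under all 4 alternatives tried, with odds ratios of 1.97 to 3.35. The summits were led by that at mir-5549 (114), whose peak is shared with eef-1A.1, and that at mir-52 (68.6). Other noncoding RNA genes had 373 summits (18.2% against 9.43%, odds ratio 2.13), and ribosomal RNA genes had 0.

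The sequence at the summits was rich in G and C and held few homeodomain core sites. The palindrome TAATTA, the textbook core of homeodomain binding, was present in 27 of 2052 summit windows of 100 bp (1.32%, 0.906 to 1.91) and in 5.31% of windows centred 300 bp to the right (ratio 0.248, exact McNemar test, adjusted p = 6.84e-13 over 22 motifs). The variants TAATTG (2.44% against 9.21%) and TAATCC (1.41% against 3.61%) were lower too. CTGCGTCT was present at 14.8% of summits and 0.682% of flanks (ratio 21.7, exact test, adjusted p = 1.56e-73), GCGCGC at 11.6% and 0.731% (15.9), the Sp1-like CNCCGCCC at 3.51% and 0.634% (5.54) and GAGAGA at 30.6% and 6.58% (4.64). The mean G and C content was 49.0% ± 6.78 (SD over 2052 windows) at summits, 35.3% ± 8.41 at flanks and 37.6% ± 8.71 at relaxed-only summits.

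Of the other motifs, CACGTG (ratio 1.84), CAGCTG (1.73), TGACGTCA (2.71) and the tRNA A box TRGYNNARNNG (1.42) were higher at summits. TGATAA (0.177), TTTCAG (0.188), TATAAA (0.279), the T block (0.367) and CCAAT (0.806) were lower. TGACGTCA kept its call under 1 alternative alone, the one without replicate 1, and the A box and CCAAT lost theirs with the stricter peak threshold (ratios 1.23 and 0.846). The A box call was lost without the X chromosome too (1.18). No difference passed for TGATTGAT (0.273), GTTCGANNC (0.913), TGASTCA (0.895), GTAAACA (1.03), AGGTCA (0.791) and ATTTGCAT (0.692). With 200 bp windows GTTCGANNC, the tRNA B box, passed as higher (2.71, exact test, adjusted p = 1.55e-07). TGATTGAT did pass as lower under 4 alternatives, with the peaks of replicate 2 alone (0.0833), the left flank (0.136), relaxed-only summits (0.186) and without the X chromosome (0). Against relaxed-only summits, AGGTCA (0.639) and ATTTGCAT (0.492) passed as lower as well.

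Most of these calls were lost when the flanks had a similar G and C content. In the 387 peaks whose flank had a G and C content within 5 percentage points of the summit, an alternative chosen after seeing the data, GAGAGA (ratio 2.94), CTGCGTCT (7.17) and GCGCGC (8.50) still passed as higher, and TGATAA (0.290) and TTTCAG (0.239) as lower. GTAAACA newly passed as higher (ratio 10, with 10 summit and 1 flank windows, exact test, adjusted p = 0.0430). The calls lost were those of TAATTA (0.60, exact test, adjusted p = 0.525), TAATTG (0.545), TAATCC (0.615), CNCCGCCC (1.00), CACGTG (1.30), CAGCTG (1.00), TGACGTCA (1.00), TATAAA (1.00), CCAAT (0.675), the A box (0.587) and the T block (1.87), the last 2 on the other side of 1. Fewer peaks entered this comparison, so a lost call does not show that the shares were equal.

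**Figure D4:**
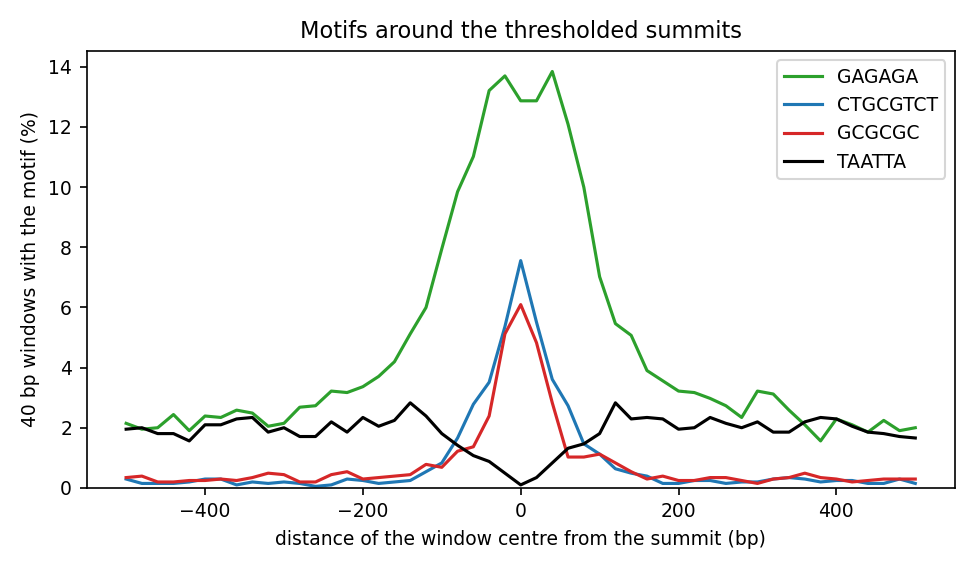
Percent of 40 bp windows that contain each motif (vertical) by distance of the window centre from the thresholded summit in bp (horizontal). CTGCGTCT and GCGCGC reach 7.55% and 6.09% at the summit, GAGAGA reaches 13.8% at 40 bp, and TAATTA has its low point of 0.0975% at the summit.

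No thresholded peak lay within 20 kb of the native ceh-82 gene (WBGene00018433, chromosome II, 1732232 to 1733291, plus strand), and 5 relaxed pooled summits did. At unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935, plus strand), a neuronal gene whose mutation is the background of the line, there were 2 thresholded and 11 relaxed-only summits within 20 kb (odds ratio 2.48, 0.549 to 11.2, Fisher's exact test, p = 0.222). The stronger of the 2 lay in an intron of unc-119, with its summit at 10905313 and a signal of 90.7, and ranked 261 and 193 in replicates 1 and 2. The other had its summit at 10896013, at the start of com-1 (signal 43.7).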

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

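The tests of base composition and of TAATTA were chosen or given their bounds only after the motif counts were seen. The tests in each replicate were chosen after the other results, and the rest were set beforehand. The test of GCGCAGGG includes the strongest X peaks, which had already been listed with their sequences, so it is not independent of them. At the highest -log10 q of the pooled relaxed list, 3.81, there were 1162 peaks outside the thresholded list, which no comparison in the report used on their own. Their signal was 14.1 to 22.3, 55.2% of their summits (52.4 to 58.1) lay in promoter windows against 70.1% of the thresholded ones, and 69.3% overlapped a relaxed peak of replicate 1 and 99.4% one of replicate 2.

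Ribosomal protein, translation factor, respiratory chain and proteasome genes had the highest odds ratios of the lists, although they account for only 120 of the 2052 peaks. A single replicate as the source of the enriched lists as a set is argued against. Lists picked with the strongest 2052 peaks of 1 replicate alone were pooled and tested with those of the other. With 7 lists picked in replicate 2, the odds ratio in replicate 1 was 11.3 (8.86 to 14.5). With 6 picked in replicate 1, neuronal genes among them, it was 13.02 in replicate 2 (10.1 to 16.8). Ribosomal protein genes made up 81 of the 264 and 247 genes, so the pooled values say less of the smaller lists. Ribosomal protein, translation factor, respiratory chain, proteasome and cell cycle lists were each picked in both replicates. Vacuolar ATPase (3.32) and heat shock protein genes (2.93) did not pass in replicate 1 and stay open. Binding through TAATTA near the summit is argued against as the source of most of the 120 peaks by the count itself, since 0.833% of them carried it within 50 bp (upper limit 4.57%). With only 27 such windows known in the whole list, most of the 120 could not have carried it, so this is no separate test. Over the whole list the 27 windows with TAATTA were close to the mean of 26.1 in 100 shuffles (range 17 to 37), which leaves open whether a few sites are bound through it. Signal at active promoters that does not depend on the tagged protein stays open and was not tested, because no library without the tag was analysed here.

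Motifs at summits were compared with 100 shuffles that keep each window's dinucleotide counts. The base composition of the windows is argued against as the whole source of CTGCGTCT, at 28.2 times the shuffle mean, GAGAGA, at 2.34 times, and GCGCGC, at 1.87 times, since each exceeded all 100 shuffles. The bound for GCGCGC and GAGAGA was first set at 3 times the highest shuffle, which neither reached, so composition may supply a large part of these. The low share of TAATTA is consistent with composition, at 1.03 times the shuffle mean and within the shuffles' range. TAATTG, a homeodomain variant, at 0.605 times, and TGATAA, at 0.544 times, lay below all 100 shuffles. That argues against dinucleotide composition as the whole source of their low counts at summits. Only summit windows were shuffled, so it does not tie the shortfall to summits. With flanks of similar G and C content, TGATAA still passed as lower (ratio 0.290), and TAATTG did not (0.545, exact McNemar test, adjusted p = 0.242).

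A small part of the X peaks outside promoters, among them the 3 strongest, shared a sequence. GCGCAGGG is the core of the motif known from recruitment sites of the dosage compensation complex. It lay within 50 bp of 11 of 162 X summits outside promoters (6.79%) and 0 of 451 autosomal ones (odds ratio 68.5, 4.01 to 1170, Fisher's exact test, p = 3.40e-07). The 3 strongest had already been listed with their sequences, so this test is not independent of them. Without those 3, 8 of 159 X summits outside promoters carried it (odds ratio 50.7, 2.91 to 883, exact test, p = 1.87e-05). A single replicate as the source is argued against, since with the strongest 2052 peaks of each replicate alone the odds ratio was 55.2 in replicate 1 (3.20 to 953) and 67.01 in replicate 2 (3.90 to 1151), with 0 autosomal summits in either. In promoter windows GCGCAGGG lay at 5 of 185 X summits (2.70%), among them the nspc-17 peak, and at 1 of 1254 autosomal ones (0.0797%), a difference that was not tested. A candidate explanation for the 11 outside promoters, and possibly for these 5, is that they are recruitment sites. Such sites may be open or highly occupied in any chromatin preparation, but no biological explanation was tested against a library without the tag.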

How the results depend on the processing

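Of 28 recomputed main values that have a test, 26 kept their direction and test result. They include the tests at ceh-82 and unc-119, which had 0 and 2 thresholded peaks within 20 kb. So few peaks made a pass unlikely there, and an unchanged result at these loci says little. Of 50 recomputed counts, 20 were equal and 45 within 1.5 times the count they replace, so calls of single lists or motifs changed within that bound, and of 8 recovery percentages 2 stayed within the Wilson interval. The replicate correlation (rho 0.594 to 0.678), the overlap of the strongest peaks (53.9% to 70.0%), the promoter odds ratio (4.10 to 7.24) and the promoter signal difference (0.15 to 0.31) kept theirs under each alternative run. Depth was not given in the sources used here, so what it limits could not be measured.

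The stricter threshold left 1026 peaks by construction. Recovery moved to 85.6% in replicate 1 and 97.2% in replicate 2 with reciprocal overlap of 50%, to 89.6% and 99.4% with summits within 100 bp, and to 98.9% and 100% with the stricter threshold. Against chromosome length, 1 chromosome was lower and the middle 33.3% of the autosomes passed with an odds ratio of 1.39, while chromosome II lay at 0.938. With peaks in the window of 1 gene, 4 lists were lower, and with flanks of similar G and C content, 4 motifs were higher and 2 lower, from 387 peaks. Those settings and the one without the X chromosome were chosen after seeing the data. At ceh-82, with 0 thresholded peaks, the odds ratio was 0.504 at 40 kb. Fewer peaks entered some of these settings, and the cause of the changes was not tested.

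These odds ratios or ratios changed side of 1, and none but GTTCGANNC at 200 bp passed a test. With the stricter threshold they were noncoding RNA gene summits (0.967), aminoacyl-tRNA synthetases (0.535), body-wall muscle (0.976), hypodermis (0.267), germline (1.14), insulin signalling (0.790) and GTAAACA (0.588). Without replicate 2 they were body-wall muscle (0.585, and 1.83 without replicate 1), hypodermis (0.496, and 1.33), germline (1.07, and 0.630), GTTCGANNC (1.18, and 1.25), TGASTCA (1.16), GTAAACA (0.892, and 1.26) and AGGTCA (1.02, and 1.06), where GTTCGANNC and AGGTCA changed side without replicate 1 too. With 500 bp windows they were histones (1.02) and hypodermis (0.965), and with 2000 bp windows hypodermis (0.865). With genes that have a relaxed summit as background they were histones (1.97), bHLH factors (1.12), body-wall muscle (0.843) and insulin signalling (0.482). Without the X chromosome they were hypodermis (0.985) and TGASTCA (1.15). With peaks in the window of 1 gene they were nuclear hormone receptors (1.11) and bHLH factors (1.72). GTTCGANNC was 1.17 with the left flank, 1.17 against relaxed-only summits and 2.71 with 200 bp windows (exact test, adjusted p = 1.55e-07), where TGASTCA was 1.53 and AGGTCA 1.07. With flanks of similar G and C content they were TRGYNNARNNG (0.587), TGASTCA (1.67), AGGTCA (1.29) and the T block (1.87).

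Among 448 other tested values, 362 kept direction and test result, 40 no longer passed and 14 newly passed, which include 4 and 1 of the 37 that changed side of 1 as given above. Peak ranks have no test, and of 219 in a single replicate 209 stayed within the strongest 2052, often at another rank, while 10 fell outside it in replicate 1. The rgef-1 peak matched no peak of replicate 1, so it has no rank there and that absence is not counted.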

Other observations

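The k-mer search, the gene name prefixes, the tests of GCGCAGGG given below and the shares of motifs by group were chosen after the report's results were seen. Peaks were also counted by the prefix of the gene name, with no fixed list of cell machinery among them. Among 175 prefixes with at least 10 protein-coding genes, 22 were higher and 19 lower (Fisher's exact test, Benjamini-Hochberg adjustment). Nuclear pore genes (npp) had peaks at 13 of 26 (odds ratio 9.14, exact test, adjusted p = 9.05e-06), DnaJ chaperone genes (dnj) at 11 of 29 (5.58, adjusted p = 0.000895), secretory pathway genes (sec) at 8 of 19 (6.63, adjusted p = 0.00319) and mitochondrial large-subunit ribosomal protein genes (mrpl) at 12 of 41 (3.78, adjusted p = 0.00519). Mediator genes (mdt) had them at 7 of 20, and RNA polymerase II subunit genes (rpb) and Integrator genes (ints) at 5 of 11 each (exact test, adjusted p = 0.0166 for each). The prefixes lin, at 14 of 47 (3.88, exact test, adjusted p = 0.00166), and unc, at 20 of 94 (2.47, exact test, adjusted p = 0.00808), were higher too. Both are names given by mutant phenotype, which does not tell what the genes encode. A peak in the windows of several genes, such as that of lin-54 and rpl-12, was counted for each gene in these prefix tests. Cytochrome P450 genes (cyp) had them at 0 of 74 and UDP-glucuronosyltransferase genes (ugt) at 0 of 67 (exact test, adjusted p = 0.00709 and 0.0132).

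Short sequences were searched on chromosomes I to III (1082 peaks) and tested on IV, V and X (970 peaks). Of 318 candidates, the 12 strongest that shared no long stretch with a stronger one were carried forward. All 12 8-mers were more frequent at summits than at flanks in the test set (exact McNemar test, adjusted p from 2.78e-34 to 2.56e-06). Summits are richer in G and C than flanks, and apart from AGACGCAG the 8-mers were not compared with shuffles or with flanks of similar content. Composition may supply part of these differences, and some 8-mers share shorter stretches, so they are not independent. AGACGCAG, the reverse complement of CTGCGTCT, led with 140 test windows that had it at the summit alone and 5 at the flank alone. GCAAACAC (52 and 2), AAACGCGC (69 and 1), GCGCTCCA (37 and 1) and AAGTGCGC (38 and 2) lay mostly in promoters, with 92.5%, 92.9%, 94.1% and 91.7% of their summits there, while 56.6% of summits with AGACGCAG did. Peaks with GCGCCAGC had a median signal of 73.7 against 38.9 without, those with AAGTGCGC 54.1 against 39.2, and those with AGACGCAG 37.01 against 40.2. The differences in signal were not tested.

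Motif content was counted by group of peaks and not tested. CTGCGTCT lay at 3 of 63 ribosomal protein peaks (4.76%) and 2 of 74 snoRNA peaks (2.70%), against 14.8% over all peaks, and GAGAGA at 43 of 102 tRNA peaks (42.2%), against 30.6%. CTGCGTCT lay at 0 of 18 translation factor peaks, 4.55% of 22 respiratory chain, 4.90% of 102 tRNA, 9.88% of 162 X peaks outside promoters, 10.5% of 19 proteasome and 16.7% of 12 cell cycle peaks. GAGAGA lay at 5.26% of proteasome, 12.7% of ribosomal protein, 13.6% of respiratory chain, 16.2% of snoRNA, 16.7% of translation factor, 30.9% of X and 33.3% of cell cycle peaks. With summits in protein-coding promoter windows left out, the odds ratios were 16.9 near tRNA genes (12.8 to 22.2) and 25.9 near snoRNA genes (17.6 to 38.2), so nearby promoters do not account for either.

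On the X chromosome, 23 of 81 GCGCAGGG sites lay under a thresholded peak (28.4%, 19.7 to 39.0), against 1 of 233 on the autosomes (0.429%, odds ratio 92.0, 12.17 to 695, Fisher's exact test, p = 4.07e-14). X summits outside promoters with the sequence had a median signal of 160, against 36.5 without it (log2 difference 2.13, two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). Without the peaks among the 15 strongest, 8 of 159 X summits outside promoters carried it (odds ratio 50.7, 2.91 to 883, exact test, p = 1.87e-05), with a median signal of 67.6 against 36.5 (log2 difference 0.785, permutation p = 0.00679). The report's hypodermis list, which did not pass (7 of 63), also named dpy-27, dpy-30 and dpy-26, dosage compensation genes, with peaks at their starts. The dpy-27 peak ranked 13969 of 16551 in replicate 1. Genes with the prefix dpy had peaks at 4 of 25 (odds ratio 1.73, exact test, adjusted p = 0.528). Dosage compensation genes were not counted as a set, so members without a peak are not given. No test here ties the peaks of dpy-27, dpy-30 and dpy-26 to the X sites.

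The number of relaxed summits around the native loci was not high. Within 20 kb of ceh-82 there were 5 relaxed pooled summits, against a 95th percentile of 23 in 10000 random windows of that size, and within 20 kb of unc-119 there were 13, against 25. Of the thresholded summits, 2 lay within 10 kb of unc-119 (odds ratio 4.54, 0.916 to 22.5, exact test, p = 0.0995), and 1 of them, ranked 220, lay inside the gene. These counts do not tell whether copies of unc-119 in the line raise the signal of that peak, which was not tested.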
